A study of Musa acuminata with 9 samples.

How the data were processed

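The samples were roots of banana (Musa acuminata) grown in hydroponic culture for 50 days. Per the labels' protocols, the root ends were severed and the roots were dipped for 2.5 h in a spore solution of Fusarium oxysporum f. sp. cubense, the fungus of banana wilt, of race 1 (Foc1) or race 4 (Foc4). Mock roots were dipped in PDB, the culture medium without the fungus. The liquid that carried the spores is not stated, so the fungus and the dipping liquid cannot be told apart. Roots were taken at 3, 27 and 51 h. Each of the 9 conditions had 1 library, so there were no replicates of a condition. The tissue label of every sample names several organs besides roots, while the design text of the series names roots, and the design text was followed here.

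The deposited table gave values in CPM, read counts scaled to the library total, for 14906 rows, per the file headers. TopHat is the alignment tool named in the submitters' processing notes; its version and the genome build are not given in the sources used here. The rows carried banana gene models or CUFF identifiers (578 rows), with a symbol and a description supplied by the authors in the same table. Each gene model could have a sense and an antisense row (10118 sense and 4788 antisense rows, 3495 genes with both). How the authors counted strands is not given in the sources used here, so antisense and overlapping genes are uncertain, as are near-identical copies within gene families. The lowest maximum of any row was 7.53 CPM, so genes that stayed below that level in every library are not in the table. The RefSeq gene table at hand belongs to another assembly without these locus names and was not used.

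Within each library the values were whole multiples of a smallest step, taken as the worth of 1 read. Of all 134154 values, 99.98% lay within 0.1 of a whole number of reads, and the lowest library share was 99.9%. The step gave totals of 447247 (Foc1, 27 h) to 1460627 reads (Mock, 27 h), a 3.27-fold range. If the authors scaled the libraries before deposit, these totals are scaled totals and not the sequenced depth. The listed rows summed to 71.8% to 96.9% of the total that CPM refers to.

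Sense rows were analysed. Values were used as deposited, on the scale log2(CPM + 1), where a fold change of a low gene is understated. Single times were compared by the count of genes with a difference of at least 1 (2-fold), among genes with at least 1 CPM in 1 of the 2 libraries, with no p-value. The count that counting noise alone gives came from 20 Poisson draws per library around the mean of both. Ratios of reads carry an exact 95% interval, which covers counting error only. A library with 0 reads was set at a floor of 3 reads per library, and the fold is then a lower bound.

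Across times, limma 3.58.1 in R 4.3.3 fitted treatment and time as additive terms to all 9 libraries (4 residual degrees of freedom), on genes with at least 1 CPM in at least 3 libraries, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Times stand in for replicates of a treatment and treatments for replicates of a time. Nothing states that the libraries came from separate pools of plants, so the p-values measure only the spread between these libraries. A further limma model was chosen after seeing the data. It held time, inoculation at 3 h, and inoculation at 27 and 51 h, with the races as repeats, and it also tested the difference between the late and the 3 h effect (4 residual degrees of freedom). Its spread comes from differences between the races and between the late times, not from repeated mock libraries.

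Gene lists were defined by words in the authors' descriptions: PR proteins, chitinases, beta-1,3-glucanases, thaumatins, class III peroxidases, WRKY factors, ethylene response factors, ethylene synthesis, jasmonate synthesis and JAZ/TIFY, phenylpropanoid and lignin enzymes, flavonoid and stilbene-type synthases, NB-LRR proteins, receptor-like kinases, respiratory burst oxidases, glutathione S-transferases, heat shock proteins, hypoxia and fermentation, expansins and xyloglucan endotransglucosylases, pectin-modifying enzymes, aquaporins, auxin response, cytosolic ribosomal proteins, histones, photosynthesis as a marker of green tissue, and fungal annotations. Lists were tested with camera, which compares a list with all other genes, at its preset correlation and again with an estimated one, adjusted over the lists. The fry test, which asks whether a list moves on balance in 1 direction without comparing it with other genes, was run beside it. At single times the median of a list was placed among random lists of equal size and similar mean level. The spelling rules caught 4 RIN4-like genes among the NB-LRR proteins and 2 potassium channels among the jasmonate genes, and both lists were also tested without them.

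Named genes were chosen by a rule. It took the 10 largest rises and falls per treatment comparison, and where fewer passed it was filled up by genes with 1 direction at all 3 times, ranked by the smallest of their 3 differences. It also took the 3 largest rises and falls per race and time, the 2 members of each list with the largest mean difference, and the 5 largest time changes. The tests, alternatives, lists and this rule were fixed before the data were examined. The 10 largest rises and falls of the late model were added later, and other genes named after their values were seen are marked so.

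The alternatives set with them were median-ratio size factors, no filter on low values (at single times a limit of 5 CPM), a pseudocount of 0.1, limma with trend and robust variance, an adjusted p threshold of 0.10, fits without the time term, with only the 2 treatments compared or without single times or treatments, and a 4-fold size threshold. Alternatives added after seeing the data were fits of the late model with 1 race or without single libraries, edgeR 4.0.16 (quasi-likelihood) on the recovered reads, sense and antisense rows together, and rescaling to the sum of the listed rows. The fits were tested on simulated data with 100 genes changed 4-fold and 100 changed 8-fold, at a dispersion of 0.1. For Foc1 across times limma recovered 56 and 95 of them with 5 false calls among 10117 genes. For the late effect it recovered 32 and 81 with 1 false call among 10118 genes. The data were noisier, with dispersions estimated by edgeR of 0.27 across times and 0.16 in the late model. At these values limma recovered 14 and 52 with 3 false calls, and 13 and 62 with 0, so most 4-fold changes would be missed. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.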

Results

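Transcript levels were measured in 9 root libraries of banana, 1 for each of mock, Foc1 and Foc4 inoculation at 3, 27 and 51 h. The design asks how roots respond to race 1 and to race 4 of the wilt fungus over time. The implied totals at 3, 27 and 51 h were 1353895, 1460627 and 1430356 reads for mock, 1373991, 447247 and 973533 for Foc1, and 1166715, 837465 and 844814 for Foc4. A gene with 0 reads could thus stand at up to 2.05 CPM (Mock, 27 h) to 6.71 CPM (Foc1, 27 h). No row of the table carried a fungal annotation, so the fungus itself was not measured.

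Foc1 roots differed from mock roots in far more genes at 27 and 51 h than at 3 h, while Foc4 roots differed in many genes already at 3 h. Among genes of at least 50 CPM in the higher of the 2 libraries compared, 14.2% differed at least 2-fold between Foc1 and mock at 3 h, 49.2% at 27 h and 55.3% at 51 h. This choice lets in genes that are high in only 1 of the 2 libraries. For Foc4 these shares were 36.0%, 52.1% and 44.0%. The mock libraries of 27 and 51 h differed from each other in 12.4% of such genes, but those of 3 and 27 h in 41.7%. From 3 to 27 h the share was 32.7% within Foc1 and 42.6% within Foc4. From 27 to 51 h it was 20.9% within Foc1 and 25.6% within Foc4. Over all genes, Foc1 against mock gave 1408 higher and 1191 lower at 3 h, 2351 and 2744 at 27 h, and 2573 and 2657 at 51 h. Foc4 against mock gave 1955 higher and 1830 lower at 3 h, 2507 and 2554 at 27 h, and 2117 and 2232 at 51 h. Among genes of at least 50 CPM the balance was the other way in each case, with 127 higher and 257 lower, 729 and 665, and 846 and 782 for Foc1, and 379 and 668, 875 and 657, and 645 and 579 for Foc4. Counting noise alone would give 627, 1579 and 828 genes in the 3 Foc1 comparisons and 750, 967 and 968 in those of Foc4. With 1 library per condition these differences have no replicate check.

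**Figure D1:**
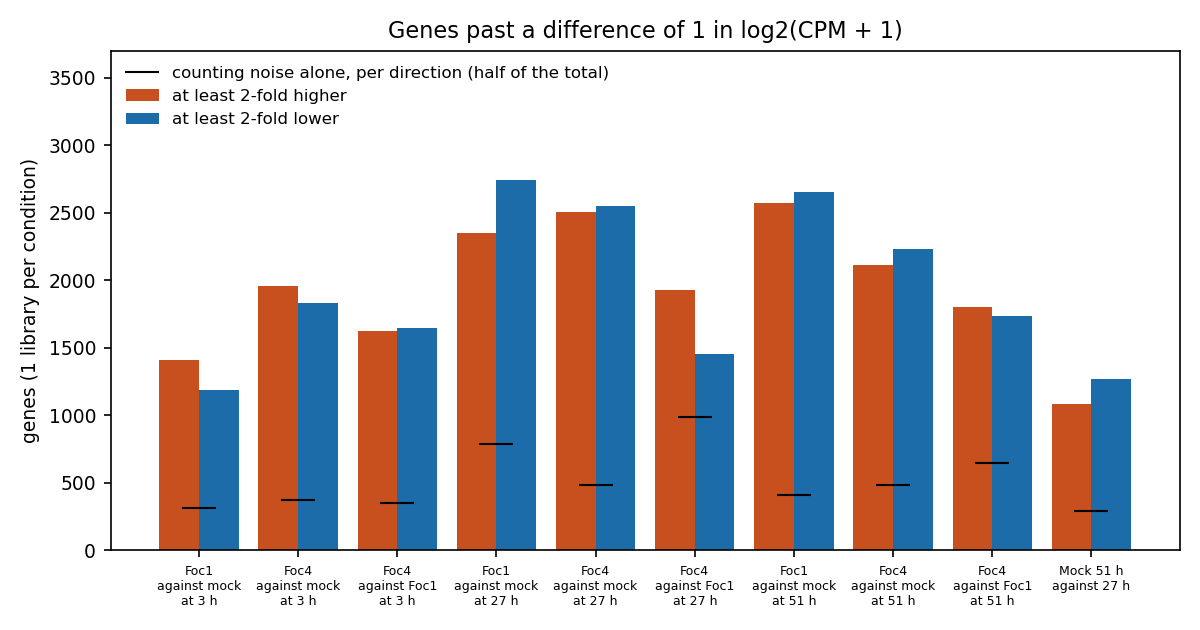
Number of genes at least 2-fold higher (orange) or lower (blue) in log2(CPM + 1) for each pair of libraries, with black lines for the number that counting noise alone gives per direction. Foc1 against mock rises from 1408 and 1191 genes at 3 h to 2573 and 2657 at 51 h, while the mock libraries of 27 and 51 h differ in 1086 and 1266 genes. Mock at 27 h against mock at 3 h, not drawn, gives 2068 higher and 2221 lower.

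In roots inoculated with race 1, the gene of pathogenesis-related protein R, tlp (GSMUA_Achr7G16510_001), a thaumatin-like defence protein, stood at 26518, 12897 and 17833 CPM at 3, 27 and 51 h. Mock roots held 3224, 1018 and 1082 CPM, so the ratios were 8.23 (95% counting interval 7.97 to 8.49), 12.7 (12.0 to 13.4) and 16.5 (15.7 to 17.4). SRG1 (GSMUA_Achr6G32920_001) had 1 read in mock at 3 h and 0 later, against 47.3, 51.4 and 67.8 CPM in Foc1, at least 32.3-fold higher at 51 h. ABCG39 (GSMUA_Achr1G08050_001), an ABC transporter of the plasma membrane family, had 0 reads in every mock library and was at least 3.61-, 6.53- and 11.8-fold higher. In the other direction, a major facilitator transporter with the symbol crnA (GSMUA_Achr11G01970_001) had 0 reads in all Foc1 libraries and was at least 4.74-, 105- and 78.5-fold lower. The receptor-like kinase At1g51860 (GSMUA_Achr2G16510_001) stood at 3.64, 2.24 and 2.05 CPM against 31.8, 80.8 and 85.3 in mock.

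None of these differences passed the planned test of Foc1 against mock across times. With limma, 0 of 10103 genes passed, 1690 had an unadjusted p under 0.05 where chance gives 505, and the smallest adjusted p was 0.0761. The edgeR test on recovered reads called 1 gene higher and 1 lower of 8384. Genes higher at all times, taken by the smallest of their 3 differences, had estimates of 5.54 ± 0.65 (log2, SE) for SRG1, 4.44 ± 0.49 for CUFF.10754.1 (an alpha/beta hydrolase), 4.28 ± 0.70 for CYP71A9, 4.22 ± 0.64 for CYP71B10, 3.94 ± 1.05 for the lichenase GN1, 3.90 ± 0.62 for ABCG39, 3.58 ± 0.57 for tlp, 3.54 ± 0.54 for Peroxidase 5 (GSVIVT00037159001), 3.06 ± 0.50 for a nucleic acid binding fragment (GSMUA_Achr9G26340_001) and 2.89 ± 0.48 for the acidic endochitinase SE2. Those lower at all times had estimates of -6.96 ± 1.07 for crnA (GSMUA_Achr11G01970_001), -4.66 ± 0.68 for sec14, -4.10 ± 0.72 for At1g51860, -4.10 ± 0.66 for the endoglucanase GLU6, -3.93 ± 0.69 for SALT, -3.83 ± 0.70 for At1g05700, -3.77 ± 0.60 for the subtilisin-like protease ARA12, -3.62 ± 0.69 for the amine oxidase maoI, -3.29 ± 0.66 for GAI1 and -3.29 ± 0.53 for At5g45780. When the 3 h libraries were left out, 567 genes were higher and 441 lower.

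As groups, ethylene synthesis and jasmonate genes were higher in Foc1, and expansins, aquaporins and cytosolic ribosomal proteins were lower, by camera with its preset correlation. The adjusted p was 0.0206 for the 10 ethylene synthesis genes (median log2 1.60), 0.00845 for the 46 jasmonate genes (0.71), 0.0136 for the 36 expansins and xyloglucan endotransglucosylases (-1.14), 0.0206 for the 23 aquaporins (-1.16) and 0.000264 for the 165 ribosomal proteins (-0.52). None of these calls held with an estimated correlation (adjusted p = 0.601 for all but aquaporins, 0.607), and fry called no list (lowest adjusted p = 0.308). Over all genes 0 members of any list passed. Adjusted over the list alone, 1 ethylene synthesis gene was higher, 0 jasmonate, aquaporin and ribosomal genes passed, 1 expansin-type gene was higher and 1 lower.

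In roots inoculated with race 4, tlp (GSMUA_Achr7G16510_001) reached 16911, 30099 and 22617 CPM at 3, 27 and 51 h, 5.25-, 29.6- and 20.9-fold above mock. CYP72A1 (GSMUA_Achr4G04400_001), annotated as secologanin synthase, held 70.3, 45.4 and 59.2 CPM against 7.39, 0 and 0.699 in mock. The expansin-like gene EXLB1 (GSMUA_AchrUn_randomG04750_001) held 36.0, 127.8 and 168 CPM against 3.69, 0.685 and 4.19. The thaumatin-like TL1 (GSMUA_Achr1G07630_001) went the other way, with 0, 2.39 and 1.18 CPM against 10.3, 24.6 and 16.8 in mock, so members of the same defence family moved apart.

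The planned test of Foc4 against mock across times also called 0 of 10103 genes with limma, with 1600 at an unadjusted p under 0.05 and a smallest adjusted p of 0.102, and edgeR called 0 of 8384 with 1350 at an unadjusted p under 0.05. The genes taken in the same way had estimates of 4.92 ± 0.65 for SRG1, 4.75 ± 0.90 for EXLB1, 4.59 ± 0.68 for CYP72A1, 4.27 ± 0.49 for CUFF.10754.1, 4.09 ± 0.64 for CYP71B10, 3.69 ± 0.62 for narX, 3.58 ± 0.50 for the nucleic acid binding fragment (GSMUA_Achr9G26340_001), 3.22 ± 0.54 for Peroxidase 5 (GSVIVT00037159001), 3.15 ± 0.51 for the dehydrin XERO1 and 3.12 ± 0.48 for SE2. On the lower side stood crnA (GSMUA_Achr11G01970_001) at -6.59 ± 1.07, sec14 at -4.38 ± 0.68 and At1g51860 at -4.30 ± 0.72, followed by glnD, At3g12360, Kif26a, TL1, PME35, ATL17 and the chitinase CHIT3 at -3.43 to -2.93. Without the 3 h libraries, 471 genes were higher and 164 lower.

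Of the lists, PR proteins, ethylene response factors, ethylene synthesis and jasmonate genes were higher in Foc4, and expansins and ribosomal proteins lower, by camera with its preset correlation. The adjusted p values were 0.0251, 0.0251, 0.0214, 0.0188, 0.0201 and 9.69e-07 in that order, with median log2 differences of 0.50, 0.78, 1.94, 0.58, -1.06 and -0.55. With an estimated correlation the adjusted p = 0.736 for all 6, and fry called no list (lowest adjusted p = 0.287). Over all genes 0 members passed. Adjusted over the list alone, 3 PR proteins, 5 ethylene synthesis and 5 jasmonate genes were higher, 1 jasmonate gene was lower, 1 expansin-type gene was higher and 1 lower, and 0 ethylene response factors and ribosomal proteins passed.

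Between the races, several gene lists stood higher in the median in Foc4 than in Foc1 roots at 51 h. Aquaporins had a median log2 difference of 1.34, with 14 of 23 at least 2-fold higher and 1 lower, class III peroxidases 1.01 (23 of 45 higher, 1 lower), expansins and xyloglucan endotransglucosylases 1.01 (18 of 36 higher, 2 lower) and chitinases 1.23 (6 of 11 higher, 1 lower). TIP2-2 (GSMUA_Achr11G04570_001), an aquaporin of the vacuolar membrane, was 8.01-fold higher in Foc4 (counting interval 5.71 to 11.5), and PRX74 (GSMUA_Achr9G11920_001), annotated as Peroxidase 1, 19.4-fold (10.6 to 39.5). Histones had 1.03 (4 of 8 higher, 1 lower), glucanases 0.71 (10 of 22, 2 lower), phenylpropanoid enzymes 0.64 (16 of 45, 2 lower) and pectin-modifying enzymes 0.39 (11 of 30, 6 lower). Ethylene synthesis had -0.32 (3 of 10 higher, 2 lower). Against mock at 51 h, the chitinase median was 1.66 in Foc1 and 1.24 in Foc4. At 3 h aquaporins, peroxidases and expansins lay the other way between the races. Their medians were -0.79 (1 higher, 9 lower), -0.54 (0 higher, 14 lower) and -0.37 (3 higher, 10 lower), while chitinases had -0.11 (2 higher, 3 lower). At 27 h the medians were 0.17, -0.34, -0.50 and 0.38 in the same order.

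No gene passed the planned test between the races across times. The limma test called 0 of 10103 genes, with 167 at an unadjusted p under 0.05 where chance gives 505, and edgeR called 0 with 37. A limma count so far below chance means that the p-values of this comparison were too large. The fit counts treatment effects that change with time as error. The 0 calls therefore do not show that the races acted alike. No list passed (lowest camera adjusted p = 0.213, lowest fry adjusted p = 0.997). Genes with 1 direction at all times had adjusted p = 1 and mostly low levels. Among them were CUFF.18832.1 (an auxin-responsive SAUR gene, 2.65 ± 0.68), Os02g0190300 (2.31 ± 0.49), UBXN7 (1.97 ± 0.55), AGD12 (1.79 ± 0.63) and Os03g0698800 (1.76 ± 0.47) on the Foc4 side, and At1g22960 (-2.52 ± 0.68), Nap1l1 (-2.14 ± 0.62), APRR5 (-2.07 ± 0.61), the lipase EXL1 (-1.98 ± 0.44) and the starch synthase SS3 (-1.85 ± 0.51) on the Foc1 side. The per-time counts of Foc4 against Foc1 were 1628 higher and 1647 lower at 3 h, 1925 and 1458 at 27 h, and 1805 and 1739 at 51 h. Counting noise alone would give 702, 1981 and 1297.

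The responses to both races ran along the same genes at 27 and 51 h. Across 10103 genes, which are not independent replicates, the log2 differences of Foc1 and Foc4 from mock had r = 0.782 (rho 0.745) at 27 h and 0.767 (0.714) at 51 h. Both differences use the same mock library, and unchanged groups give r = 0.500 and 0.498. The covariance was 2.43 at 27 h and 2.07 at 51 h against 0.637 and 0.633 for unchanged groups. At 3 h, r was 0.523 and the covariance 0.615, against 0.636 for unchanged groups. The unchanged groups carry the spread of the additive fit over all 3 times, which counts treatment effects that change with time as error. That spread is not specific to 3 h, so whether the races shared a response at 3 h cannot be judged from it. Part of the excess at the late times may come from the shared controls. Between differences that share no library, r was 0.569 (Foc1 at 27 h and Foc4 at 51 h) and 0.708 (Foc1 at 51 h and Foc4 at 27 h). The mock libraries of 27 and 51 h resembled each other (r = 0.913) and lay apart from all others. A shift common to both could therefore also give such values. Across times r was 0.884 (rho 0.853), the covariance 1.11 against 0.212, and the unchanged r 0.499. Differences at 3 h and at a late time that share no library had lower r. For Foc1 at 3 h it was 0.00223 with Foc4 at 27 h and 0.111 with Foc4 at 51 h. For Foc4 at 3 h it was 0.156 with Foc1 at 27 h and 0.293 with Foc1 at 51 h. The value across times thus does not mean that the 3 h and late responses were alike.

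At 3 h, heat shock proteins were higher and cytosolic ribosomal proteins lower in the median in inoculated than in mock roots. The mock side was 1 library, Mock 3 h, shared by both races, so a trait of that library alone could move either list. Camera called both lists at its preset correlation (adjusted p = 0.0208 and 0.00303) in the model described below, but neither with an estimated correlation (adjusted p = 0.882 for both) nor by fry (lowest adjusted p of any list 0.77). Of either list 0 members passed over all genes or adjusted over the list alone. The 48 heat shock genes had medians of 0.47 in Foc1 (14 at least 2-fold higher, 4 lower) and 0.57 in Foc4 (14 higher, 2 lower), and the cognate HSP70 (GSMUA_Achr8G20850_001) stood at 292 and 385 CPM against 131 in mock. The 165 ribosomal genes had medians of -0.22 and -0.58. Rescaling to the sum of the listed rows raised the 3 h effect of all genes by 0.238 in the median, so the sizes of both lists' differences depend on the scaling. In Foc1 the genes furthest above mock were SRG1, 64.0-fold (11.1 to 2568), CUFF.10754.1, 39.4-fold (6.68 to 1595), and the chaperonin subunit cct8, at least 8.54-fold against 0 mock reads. Furthest below mock were WRKY40 (GSMUA_Achr4G01930_001), at 0.728 CPM against 54.7, the F-box gene At1g67480, at 0 against 20.7, and the profilin PRO1, at 2.91 against 70.9. In Foc4 they were SNAPIN, at least 7.35-fold higher, with Kdm5a and the zinc transporter ZIP3 also at 0 mock reads, and on the lower side scrA (1.71 CPM against 135), CTU2 (0 against 26.6) and CML22 (1.71 against 58.4).

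A model with the races as repeats, chosen after seeing the data, called 0 of 10103 genes at 3 h with limma (590 at an unadjusted p under 0.05), while edgeR called 0 higher and 3 lower of 9814 (654 unadjusted).

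At 27 and 51 h, inoculated roots held high levels of genes that mock roots hardly expressed. The putative 3-hydroxybenzoate 6-hydroxylase xlnD (GSMUA_Achr6G07190_001) had 0 reads in mock and was at least 267-fold (Foc1) and 438-fold (Foc4) higher at 27 h, and at least 179.7- and 196-fold at 51 h. STP13 (GSMUA_Achr7G27070_001), a sugar transporter, stood at 1071 and 1217 CPM in Foc1 and Foc4 at 27 h against 7.53 in mock, and at 1224 and 703 at 51 h against 0 reads. AOX1A (GSMUA_Achr6G01170_001), the alternative oxidase of mitochondria, stood at 1270 and 954 CPM at 27 h against 3.42. The reverse held for crnA (GSMUA_Achr8G14230_001), the most abundant sense transcript of mock roots at 27 h with 36026 CPM, against 17.9 in Foc1 and 8.36 in Foc4. Mock roots held 457 CPM of it at 3 h and 8910 at 51 h, when Foc1 and Foc4 held 7.19 and 90.0.

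In the model chosen after seeing the data, 869 genes were higher and 615 lower in inoculated roots (4 libraries) than in mock roots (2 libraries) at 27 and 51 h. limma tested 10103 genes (3154 at an unadjusted p under 0.05), and edgeR called 1049 higher and 921 lower of 9814. The rises with 1 direction in all 4 differences were led by xlnD (9.04 ± 0.48, adjusted p = 7.74e-05), STP13 (8.46 ± 0.65, 0.00027), AOX1A (7.58 ± 0.57, 0.00027), MYB4 (GSMUA_Achr4G18180_001, 7.17 ± 0.55, 0.00027), CUFF.14993.1 (a transcription factor, 7.06 ± 0.64), a further MYB4 (GSMUA_Achr11G00410_001, 6.91 ± 0.58), the hydroxylase SPBC887.15c (6.82 ± 0.68), the harpin-induced domain gene SYP24 (6.77 ± 0.59), the ACC oxidase MAO1B (6.62 ± 0.59) and the hypoxia-responsive aim38 (6.60 ± 0.82). A wound-induced gene (GSMUA_Achr9G30120_001) was also among the largest at 27 h in Foc4, with 857 CPM against 1.37. The falls were led by both crnA genes (-9.88 ± 0.97 and -8.41 ± 0.59), the transmembrane gene DDB_G0273707 (-5.79 ± 0.55), PRX74 (-5.48 ± 1.04), MA4_106O17.50 (-5.37 ± 0.73), CAB40 (-5.33 ± 0.50), sec14 (-5.25 ± 0.56), the ribonuclease RNALX (-5.21 ± 1.18), the expansin EXPA30 (-5.01 ± 0.71) and PSBS (-4.98 ± 0.60). CUFF.21673.1, a proline-rich protein, stood at 4.11 CPM in Foc1 at 51 h against 3300 in mock and 695 in Foc4 and did not pass (adjusted p = 0.0613). The calls rest on 2 mock libraries that lay apart from all others, Mock 3 h included (r = 0.735 and 0.747), and 200 genes passed without the mock library of 27 h and 328 without that of 51 h.

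**Figure D2:**
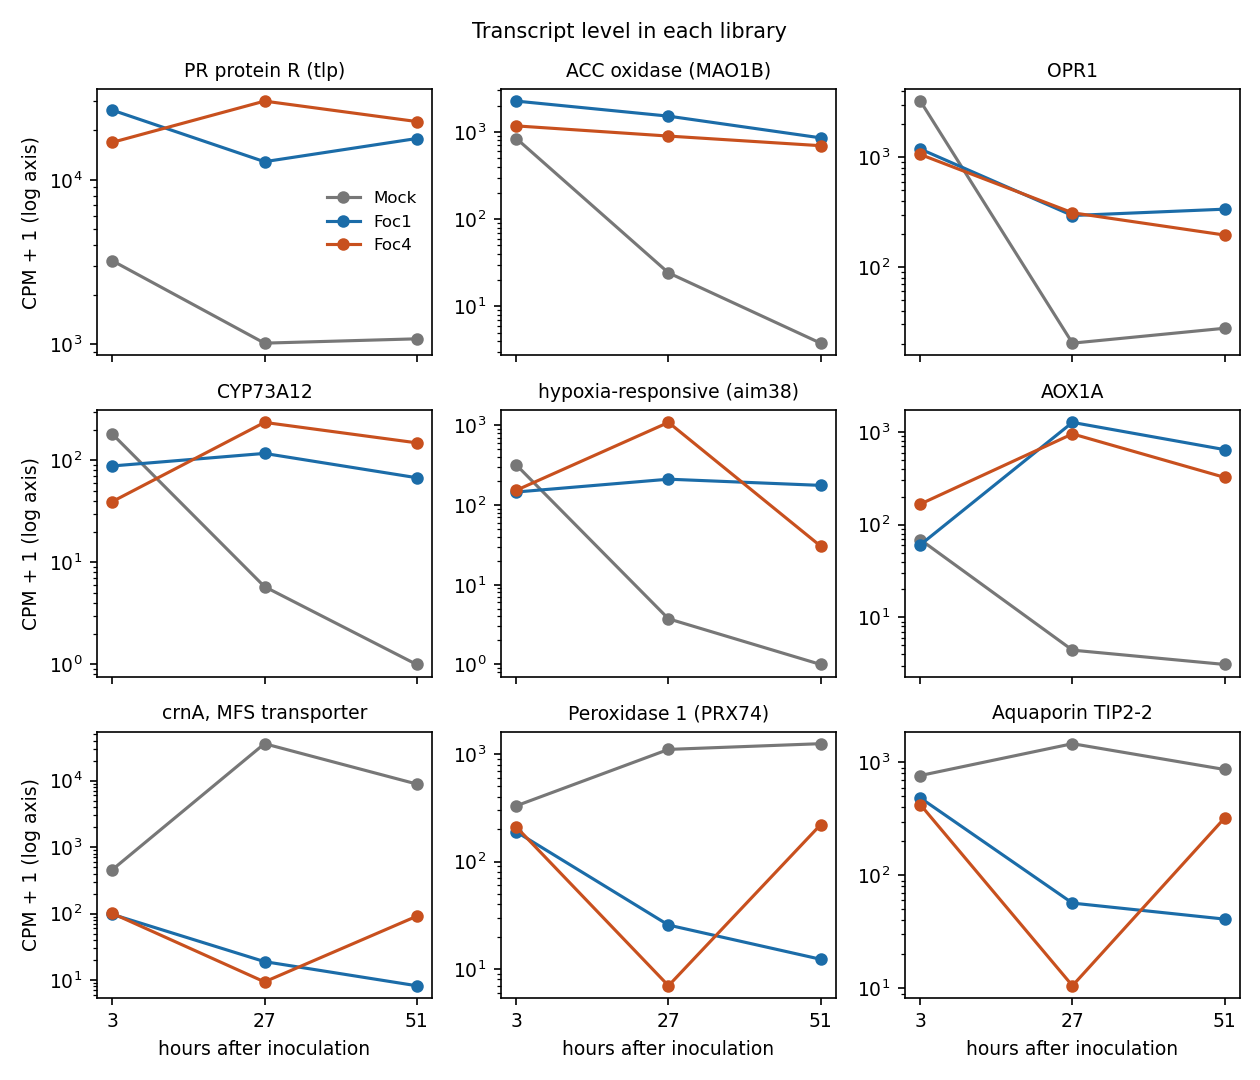
Level of 9 genes in each library in CPM + 1 on a log axis against hours after inoculation, with 1 line per treatment (mock gray, Foc1 blue, Foc4 orange). Mock roots lost OPR1, CYP73A12 and aim38 after 3 h (3245, 180 and 317 CPM at 3 h against 26.6, 0 and 0 at 51 h). PRX74 and TIP2-2 were lower in inoculated than in mock roots over 27 and 51 h together. At 3 h, 0 of 23 aquaporins, the family of TIP2-2, were at least 2-fold lower in Foc1 than in mock.

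Ethylene synthesis genes, ethylene response factors, jasmonate genes, PR proteins and WRKY factors were higher as groups at 27 and 51 h by camera with its preset correlation (adjusted p = 0.00211, 0.000788, 0.000788, 0.0213 and 0.0457). None was with an estimated correlation (adjusted p = 0.446 for all 5), and by fry the adjusted p values were 0.0104, 0.0253, 0.0233, 0.027 and 0.0366. PR proteins and WRKY factors were uneven. Their medians for Foc1 and Foc4 at 27 h, then at 51 h, were 0.78, 2.14, 0.99 and 0.32 for PR proteins and 0.20, 1.01, 0.34 and 0.42 for WRKY factors. The other lists had medians of at least 0.45 in each. Of the 10 ethylene synthesis genes 6 were higher and 0 lower (adjusted over the list alone 7 and 1), including the ACC oxidases MAO1B (GSMUA_AchrUn_randomG26960_001), at 1514 and 894 CPM in Foc1 and Foc4 at 27 h against 23.3 in mock, and MAO1B (GSMUA_AchrUn_randomG20430_001, 4.60 ± 0.74). Of 40 ethylene response factors 14 were higher and 1 lower (adjusted over the list alone 17 and 4), with ERF1B at 5.54 ± 0.59 and ERF071 at 5.07 ± 0.60. Of 46 jasmonate genes 14 were higher and 2 lower (adjusted over the list alone 15 and 3), with OPR1, an enzyme family of jasmonate synthesis, at 3.56 ± 0.46 and a lipoxygenase (Os04g0447100) at 3.85 ± 0.48. Of 15 PR proteins 5 were higher and 0 lower, over all genes and adjusted over the list alone, with tlp (GSMUA_Achr7G16510_001) at 4.24 ± 0.51 and CHI4 at 3.49 ± 0.57. This list was meant for PR proteins other than chitinases, glucanases and thaumatins. The words of the descriptions still placed the thaumatin-like tlp in it, so the defence lists are not fully separate classes. Of 56 WRKY factors 11 were higher and 3 lower (adjusted over the list alone 12 and 4), with WRKY40 (GSMUA_Achr10G06050_001) at 5.85 ± 0.60 and WRKY6 at 3.59 ± 0.45.

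Flavonoid synthases, phenylpropanoid enzymes and hypoxia genes were higher over both late times by camera with its preset correlation (adjusted p = 0.00446, 0.0213 and 0.0213). None was with an estimated correlation (adjusted p = 0.446, 0.575 and 0.48), and by fry (0.0348, 0.0705 and 0.0357) the phenylpropanoid list did not pass. The single comparisons were uneven. The medians for Foc1 and Foc4 at 27 h, then at 51 h, were 0.27, 0.99, 1.35 and 1.15 for flavonoid synthases, 0.64, 0.00, 0.18 and 1.35 for phenylpropanoid enzymes, and 1.10, 1.65, 0.44 and 0.68 for hypoxia genes. Of 24 flavonoid and stilbene-type synthases 10 were higher and 0 lower (adjusted over the list alone 12 and 1), with ANS at 4.71 ± 0.58 and DFRA at 3.75 ± 0.89, both enzymes of anthocyanin synthesis. Of 45 phenylpropanoid and lignin enzymes 14 were higher and 1 lower (adjusted over the list alone 16 and 5). The cinnamate hydroxylases CYP73A12 (GSMUA_Achr9G14110_001) and CYP73A12 (GSMUA_AchrUn_randomG27040_001), which act early in the pathway, were higher by 5.75 ± 0.64 and 4.59 ± 0.58. Of 24 hypoxia and fermentation genes 9 were higher and 2 lower (adjusted over the list alone 10 and 3). The alcohol dehydrogenase ADH1 (GSMUA_Achr8G29470_001) stood at 186 and 1666 CPM in Foc1 and Foc4 at 27 h against 4.11 in mock (6.25 ± 0.87), and aim38, annotated as hypoxia-responsive, at 210 and 1089 against 2.74.

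Expansins, aquaporins and cytosolic ribosomal proteins were lower over both late times by camera with its preset correlation (adjusted p = 0.000788, 0.00525 and 0.000591). None was with an estimated correlation (adjusted p = 0.48, 0.575 and 0.528) or by fry (adjusted p = 0.0564, 0.156 and 0.0546). In Foc4 at 51 h expansins and aquaporins lay closer to mock. The medians for Foc1 and Foc4 at 27 h, then at 51 h, were -1.71, -2.51, -1.84 and -0.41 for expansins and xyloglucan endotransglucosylases, -1.94, -1.99, -1.57 and -0.18 for aquaporins, and -0.36, -0.74, -0.84 and -0.49 for ribosomal proteins. Of 36 expansins and xyloglucan endotransglucosylases, which loosen and remodel cell walls, 10 were lower and 3 higher (adjusted over the list alone 17 and 3), with EXPA30 at -5.01 ± 0.71 and EXLB1 against the group at 5.96 ± 0.58. Of 23 aquaporins 2 were lower and 0 higher (adjusted over the list alone 7 and 0), TIP2-2 at -4.41 ± 1.00 and, named after its value was seen, PIP1-2 (GSMUA_Achr5G12400_001) at -2.30 ± 0.66, while PIP2-6 did not pass (-2.24 ± 1.07). Of 165 cytosolic ribosomal proteins 6 were lower and 2 higher, 0 adjusted over the list alone, with RPS9C at -2.09 ± 0.56 and RPL27AC, which did not pass, at -2.66 ± 0.86. Of 8 photosynthesis genes, markers of green tissue, 3 were lower and 1 higher (adjusted over the list alone 4 and 1). The camera adjusted p was 0.0597, or 0.446 with an estimated correlation, and the fry adjusted p 0.0366. The list's median was -1.74 over both late times. For Foc1 and Foc4 it was -3.45 and -1.26 at 27 h, and -1.48 and -1.70 at 51 h. CAB40, a chlorophyll-binding protein, stood at 0, 26.0 and 83.9 CPM in mock at 3, 27 and 51 h and at most 1.03 CPM in inoculated roots, and PSBS at 2.22, 36.3 and 71.3 against at most 2.37. The higher gene, named after its value was seen, was RBCS (GSMUA_Achr7G15900_001), the small subunit of Rubisco, at 2288 CPM in Foc4 against 359 in mock at 27 h.

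Other lists held members that moved both ways, with camera adjusted p values of 0.17 to 0.932. Counts of higher and lower members over all genes, then adjusted over the list alone, were 3 and 1, then 5 and 2 of 11 chitinases, and 1 and 3, then 1 and 3 of 22 beta-1,3-glucanases. They were 2 and 3 in both of 10 thaumatins, 8 and 6, then 11 and 11 of 45 peroxidases, and 25 and 25, then 35 and 29 of 193 receptor-like kinases. The chitinase SE2 (2.94 ± 0.48) and a thaumatin-like tlp (GSMUA_Achr6G31470_001, 6.07 ± 0.59) were higher, and TL1 (-3.02 ± 0.49), the peroxidases PRX74 (-5.48 ± 1.04 and -4.77 ± 0.75), and the glucanase At1g32860 (-2.91 ± 0.58) lower, while the glucanase At2g27500/F10A12.18 was higher (2.18 ± 0.62) and CUFF.40341.1, an acidic endochitinase, did not pass (2.92 ± 0.96). Among receptor-like kinases, At1g74360 was higher (5.20 ± 0.44) and At1g51860 lower (-4.94 ± 0.60), and the list's mean (-0.02) and median (0.07) differed in sign.

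The remaining defence and growth lists gave 1 higher and 1 lower of 13 NB-LRR proteins (RPP13L4, 2.63 ± 0.53, and RGA1, -3.08 ± 0.65), over all genes and adjusted over the list alone. Of 10 respiratory burst oxidases 4 were higher and 0 lower by either count, including RBOHC (GSMUA_Achr6G11760_001, 2.32 ± 0.44) and RBOHC (GSMUA_Achr10G17310_001, 1.94 ± 0.49). Of 19 glutathione S-transferases 4 were higher and 0 lower (adjusted over the list alone 5 and 1), with GSTU6 at 3.16 ± 0.51 and PARA at 2.93 ± 0.48, and the list's median (-0.08) and mean (0.50) differed in sign. Of 48 heat shock proteins 1 was higher and 0 lower by either count, HSP70 (GSMUA_Achr8G20850_001, 3.17 ± 0.51), and the stromal HSP70 (GSMUA_Achr9G07750_001, -2.39 ± 0.84) did not pass. Of 30 pectin-modifying enzymes 2 were higher and 6 lower by either count, with PME35 at -3.71 ± 0.75 and the pectinesterase inhibitor CUFF.10581.1 at 3.67 ± 0.52, and the list's median (0.02) and mean (-0.15) differed in sign. Of 46 auxin response genes 2 were higher and 6 lower (adjusted over the list alone 2 and 8), with GH3.17, an auxin-conjugating enzyme, at -4.89 ± 0.77 and CUFF.2800.1 at -3.34 ± 0.59. Of 8 histones 0 were higher and 2 lower by either count, H2B.11 (-2.70 ± 0.68) and SlH4 (-2.27 ± 0.55).

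**Figure D3:**
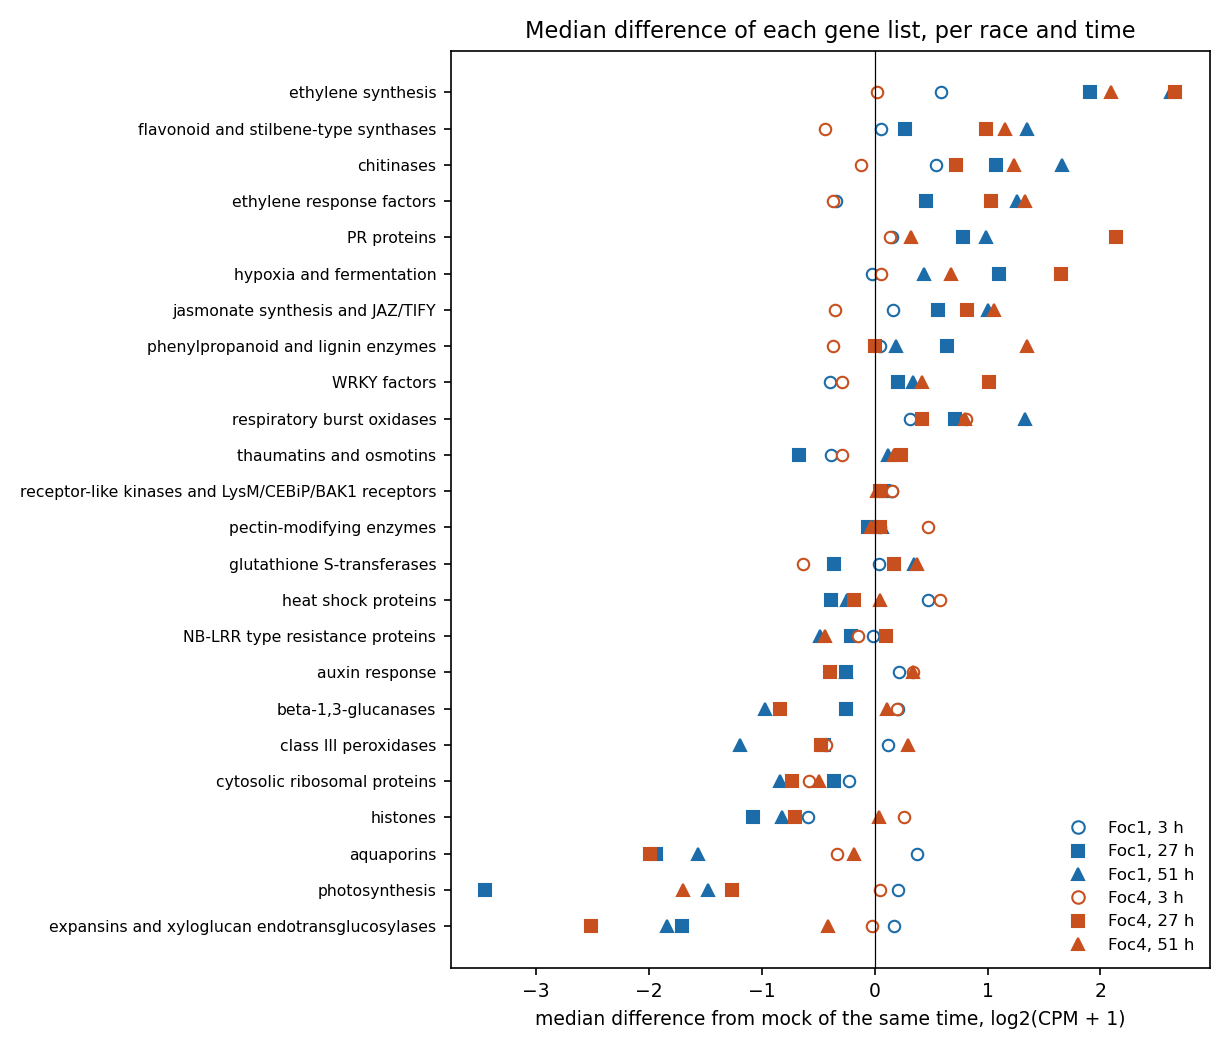
Median difference from the mock library of the same time in log2(CPM + 1) for each gene list, with open circles for 3 h, squares for 27 h and triangles for 51 h, Foc1 in blue and Foc4 in orange. Ethylene synthesis lies at 1.91 and 2.66 at 27 h and 2.63 and 2.09 at 51 h, and expansins and xyloglucan endotransglucosylases at -1.71 and -2.51 at 27 h and -1.84 and -0.41 at 51 h.

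Over time, many genes changed within each treatment, while few passed the test of a change shared by all treatments. From 3 to 27 h, 4289 genes in mock, 4196 in Foc1 and 4357 in Foc4 differed at least 2-fold. Counting noise alone would give 613, 1531 and 1017. In the test, time changes that differ between treatments count as error. Most of the genes that passed fell after 3 h. BX1 (GSMUA_Achr10G08680_001), an indole-3-glycerol phosphate lyase, went from 230.4, 249.6 and 139.7 CPM at 3 h in mock, Foc1 and Foc4 to 2.10, 7.19 and 14.2 at 51 h. With limma, 2 genes rose and 6 fell at 27 h against 3 h, and 2 rose and 11 fell at 51 h against 3 h, of 10103 tested. At 51 h the largest rise was CUFF.10754.1 (5.32 ± 0.49, adjusted p = 0.022), and the falls included BX1 (-4.79 ± 0.64, 0.036), the kinase mkkA (-4.77 ± 0.64, 0.036), the WRKY gene CUFF.38779.1 (-4.51 ± 0.59, 0.036), the boron transporter BOR4 (-4.39 ± 0.52, 0.0285) and C7 (-4.37 ± 0.51, 0.0285). No gene passed in either time comparison when any 1 treatment was left out.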

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

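The test of library labels was chosen after the late difference was seen, and the tests of depth, composition and sample splits before its results were seen. The 1484 genes that differed between inoculated and mock roots at 27 and 51 h come from a model that was itself chosen after seeing the data. After all libraries were thinned to 447247 reads, 835 of them (56.3%) were called again and all 1484 had the same direction. For the 649 calls that ended, the median size went from 2.28 (median SE 0.56) to 2.15 (0.71) in log2, so these calls ended mainly because the spread grew. With median-ratio scaling 1460 were called again, and with rescaling to the sum of the listed rows 1386. All 6 libraries of 27 and 51 h correlated best with a library of their own kind, mock or inoculated (Mock 27 h with Mock 51 h, r = 0.913). Foc1 27 h lay closest to Foc4 27 h (r = 0.87), and Foc1 51 h and Foc4 27 h to each other (r = 0.874). The labels of the races were therefore not checked by this test. Mock 3 h lay closer to the inoculated libraries of 27 and 51 h (r = 0.749 to 0.795) than to the late mock libraries (0.735 and 0.747), so a difference of the late mock libraries that does not come from inoculation is open. Of the 15 ways to choose 2 of these 6 libraries as mock, only the real choice gave any gene (highest other 0), and 15 splits are too few for a share under 0.05. Any other choice also puts a late mock library among the inoculated ones, so the gap between them enters the spread. Because the model was chosen after seeing the data, this outcome adds no support. Mock roots lay in PDB and the liquid of the spores is not stated, so a response to the dipping liquid is open, and a mock dipped in that liquid without spores would separate it.

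Both tests of the course over time were chosen after the genes had been seen. Of the genes higher in both races at 27 h, 1755 in number, mock roots had lost much of the 3 h level by 51 h, with a median log2 difference of -1.25 against -0.0369 to 0.0754 for random sets. The races had medians of 0.383 in Foc1 (random -0.227 to -0.0815) and -0.145 in Foc4 (random -0.118 to 1.81e-06), with genes on both sides: 31.9% at least 2-fold higher and 17.2% lower in Foc1, 21.6% and 27.2% in Foc4. In mock 55.1% of these genes were at least 2-fold lower and 7.24% higher, so the largest move in the median was the fall of mock. Since genes of both races moved both ways, neither a level kept from 3 h nor an induction after 3 h describes the whole group. With 1 library per condition, the 2 courses cannot be told apart for single genes. Of the 1657 genes lower in both races at 27 h, Foc1 had a median of -1.05 between 3 and 51 h (51.5% at least 2-fold lower), mock 0.618 and Foc4 -0.0745. OPR1 went from 3245 to 26.6 CPM in mock between 3 and 51 h, while AOX1A stood at 59.7 CPM at 3 h and 645 at 51 h in Foc1.

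The antisense test was chosen before its result was seen. Of 4766 antisense rows 509 differed between inoculated and mock roots at 27 and 51 h (362 higher, 147 lower, limma with Benjamini-Hochberg adjustment, 1231 at an unadjusted p under 0.05). Across 406 genes with at least 20 CPM on both strands, the antisense and sense differences had r = 0.902, though genes are not independent replicates. Of the 509, 412 had a sense row, 311 of which also differed, all in the same direction. Reads of the sense strand counted as antisense could give this. The other 97 had no sense row in the table, so the correlation says nothing about them, and the strand protocol would tell.

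For the planned comparisons, 10 of 10 sample splits gave as many genes as the real one for Foc1 against mock, 10 of 10 for Foc4 against mock and 10 of 10 for Foc4 against Foc1, since the real count and the highest other were 0. For 27 h and for 51 h against 3 h, 1 of 10 splits did (8 and 13 genes, highest other 0 for both). Such splits are too few for a share under 0.05.

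The effect of inoculation at 27 and 51 h differed from that at 3 h for 124 genes (112 higher and 12 lower, limma with Benjamini-Hochberg adjustment), in the model chosen after seeing the data. No gene passed without Mock 27 h, Mock 51 h, Foc1 3 h or Foc4 3 h, or with either race alone. By camera it differed for 11 lists, none of them with an estimated correlation (adjusted p of 0.339 to 0.5) or by fry (lowest adjusted p = 0.0862). The mock side of the 3 h effect was 1 library, Mock 3 h, so a trait of that library alone could move these differences. The median differences in log2 were 1.97 for ethylene synthesis, 1.70 for ethylene response factors, 1.42 for flavonoid synthases, 1.17 for hypoxia genes, 1.04 for WRKY factors, 0.809 for jasmonate genes, 0.561 for glutathione S-transferases, 0.395 for phenylpropanoid enzymes, -1.81 for aquaporins, -1.82 for expansins and -2.15 for photosynthesis genes. Among single genes the difference was 10.1 for SPBC887.15c, 9.19 for the wound-induced gene (GSMUA_Achr9G30120_001), 8.43 for xlnD, 8.21 for STP13, 8.01 for SYP24, 7.69 for aim38, 7.36 for CYP73A12 (GSMUA_Achr9G14110_001), 7.08 for MYB4 (GSMUA_Achr4G18180_001), 7.04 for AOX1A, 6.41 for ERF1B, 6.29 for CUFF.14993.1, 6.13 for ERF071 and 6.07 for At1g74360. It was 5.67 for MAO1B (GSMUA_AchrUn_randomG26960_001), 5.51 for WRKY40 (GSMUA_Achr10G06050_001), 5.33 for CYP73A12 (GSMUA_AchrUn_randomG27040_001), 5.28 for MYB4 (GSMUA_Achr11G00410_001), 5.24 for ANS, 5.10 for OPR1, 4.51 for the lipoxygenase (Os04g0447100), 4.32 for WRKY6, -5.08 for cct8 and -5.33 for CAB40.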

How the results depend on the processing

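With limma trend and robust variance, 33 genes passed for Foc1 against mock across times, 32 for Foc4 against mock, 65 for 27 h and 53 for 51 h against 3 h, 1 for either race against mock at 3 h and 313 for the 27 and 51 h effect minus 3 h effect (here the difference), in place of 0, 0, 8, 13, 0 and 124. An adjusted p threshold of 0.10 gave 36 for Foc1, 80 and 82 for 27 and 51 h, 2296 for either race against mock at 27 and 51 h (here the late effect) in place of 1484, and 287 for the difference. A pseudocount of 0.1 gave 4 and 4 for the times, 849 for the late effect and 75 for the difference. With edgeR on the recovered reads, 2 genes passed for Foc1, 15 for 27 h, 3 for inoculation at 3 h and 436 for the difference. Sense and antisense rows together gave 3 for 27 h. Rescaling to the sum of the listed rows gave 2 for Foc1 and 50 for the difference, and it shifted all log2 values by 0.238 at 3 h and -0.132 at the late times in the median. Without the time term 1 gene passed for Foc1. Leaving out single times gave 0 to 1008 for Foc1 and 0 to 635 for Foc4, the highest without 3 h. Leaving out mock, Foc1 or Foc4 gave 0 for both time comparisons. Leaving out single libraries gave 200 (without Mock 27 h) to 1618 (without Foc4 51 h) for the late effect, with 328 without Mock 51 h and 931 without Foc1 51 h. For the difference it gave 0 (without Mock 27 h, Mock 51 h, Foc1 3 h or Foc4 3 h) to 102, with 35 without Foc1 51 h, 57 without Foc4 27 h and 76 without Foc4 51 h. Without Mock 3 h the effect at 3 h could not be estimated. With Foc4 and mock alone 677 genes passed for the late effect, and with either race alone 0 for the difference. At a 4-fold threshold the counts at 3, 27 and 51 h were 565, 2253 and 2298 for Foc1 against mock, 969, 2204 and 1573 for Foc4 against mock, and 663, 928 and 844 for Foc4 against Foc1. Camera with an estimated correlation called 0 lists in place of 5 for Foc1, 6 for Foc4, 2 at 3 h, 11 for the late effect and 11 for the difference. The similarity of the races was 0.705 at 27 h, 0.727 at 51 h and 0.837 across times with a pseudocount of 0.1, and 0.543 at 3 h, 0.808 at 27 h, 0.787 at 51 h and 0.905 across times among genes of at least 5 CPM. Without the wrongly caught genes the median at 3 h turned from -0.11 to 0.02 for NB-LRR proteins and from -0.01 to 0.01 for jasmonate genes, and neither list passed. Why the settings moved these values was not tested. No paired analysis was possible because no label links libraries of the same plants, and time was the only block that the fits could hold.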

Other observations

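Genes of nitrate and ammonium uptake and assimilation were lower in the median in inoculated roots, at 3 h and at 27 and 51 h. This list was chosen after the values of both crnA genes and of the glutamine synthetase GS1-2 (GSMUA_Achr1G22290_001) had been seen. At the late times 10 of 24 members were lower and 2 higher (adjusted over the list alone 11 and 3), with a median log2 of -1.24 (-0.822 without the 3 members seen beforehand) and a camera p of 0.000800, or 0.0962 with an estimated correlation. Of the members seen beforehand, GS1-2, which binds ammonium into glutamine, stood at 559 and 377 CPM in Foc1 and Foc4 at 27 h against 8379 in mock. Mock was highest at 27 h, with 2755 CPM of GS1-2 at 3 h and 2535 at 51 h. At 51 h GS1-2 stood at 322 and 644 CPM in Foc1 and Foc4. The glutamate synthase GLT1 (GSMUA_Achr8G28000_001) stood at 58.1 and 51.3 against 715 at 27 h, and at 64.7 and 42.6 against 424 at 51 h. The ammonium transporter AMT3-1 (GSMUA_Achr5G26070_001, 3.41 ± 0.48) and the nitrate reductase NIA1 (GSMUA_Achr9G15480_001, 3.45 ± 0.80) went the other way. Without the seen members the camera p was 0.0326 for 21 members. At 3 h the median of the list was -0.648, with a camera p of 0.0025, or 0.123 with an estimated correlation and 0.0396 without the seen members. Of its members 0 passed at 3 h over all genes and 1 adjusted over the list alone. The mock side at 3 h was 1 library, Mock 3 h, so a trait of that library alone could move the list. For the difference between the late and the 3 h effect the camera p was 0.0259, or 0.224 with an estimated correlation and 0.247 without the seen members.

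Among 689 words of the descriptions tested, TIFY was frequent on the higher side at 27 and 51 h, with 9 of 18 genes higher and 1 lower where 1.55 higher would be expected (adjusted p = 0.00135, exact hypergeometric test over genes). So were oxidase with 20 of 73 (4 lower, 6.28 expected, 0.00135) and chalcone synthase with 6 of 10 (0 lower, 0.86 expected, 0.00851). On the lower side were LRR receptor-like genes with 17 of 73 (10 higher, 4.44 expected, 0.000763), cytochrome P450 with 11 of 47 (9 higher, 2.86 expected, 0.0156) and microtubule-associated genes with 5 of 10 (0 higher, 0.609 expected, 0.0184). LRR receptor-like and P450 genes thus went both ways. The test treats genes as independent, which genes regulated together are not. It used the same calls as the gene lists above. TIFY genes are members of the jasmonate list and chalcone synthases of the flavonoid list, and respiratory burst oxidases also carry the word oxidase. These words are therefore not separate support for those lists.

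The cause of the lower nitrogen genes was not tested, and the nitrogen content of the dipping liquids is not stated. Measuring these genes in roots dipped in each liquid without spores, with 3 or more pools per condition, would test the part of the liquid.

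The contrast between the races in aquaporins and peroxidases turned from 3 h to 51 h, and 1 library per condition cannot tell it from a difference in timing. Sampling each race at closer times with repeats would test that.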
